A study of Mus musculus with 2 samples.

How the data were processed

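Long-read RNA sequencing was carried out by the authors on total RNA of the adrenal gland of female B6CASTF1/J mice, the first-generation cross of C57BL/6J and CAST/EiJ, at 25 days of age. The labels give 1 group of 2 libraries, called biological replicates 1 and 2, and no treatment, time course or second tissue, so no condition could be compared. The descriptions of both libraries name the same animal, whereas the descriptions of the tissue name a different animal for each; the text follows the replicate numbers and the tissue descriptions.

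The values are counts: per the file headers, each deposited table gives whole reads per transcript model in 1 library, and it lists models with at least 1 read. The authors aligned the reads to the mouse genome build mm10 and assigned them to the GENCODE M21 annotation extended by models named by the program TALON, each library on its own. The aligner and the versions of the authors' programs were not given in the sources used here. The deposited annotations give the exons of every model as start and end positions, and the tables give its number of exons and length in bases. All gene identifiers of annotated genes were found in the GENCODE M21 reference, which gave their gene type, chromosome, start and end. Of the 21297 annotated transcripts with reads, 21289 had the same position as in the reference.

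The deposited classes were used as given. They are annotated transcripts, incomplete splice matches (models whose introns are a contiguous part of an annotated chain), unannotated combinations of annotated splice sites, models with at least 1 unannotated splice site, genomic models (within a gene but without its splicing, mostly of 1 exon), antisense models and intergenic models. Reads on the added ERCC control RNAs (Ambion mix 1) were counted apart and left out of every other result. The Lexogen SIRV controls named in the labels were not analysed here. Genome sequence was not used here, so splice-site motifs and runs of A were not examined, and neither were the alleles of the parental strains.

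A gene's count was the sum of all models that the files assign to that annotated gene. Levels are given as CPM, the gene's reads scaled to the library's reads on annotated mouse genes, 397176 in replicate 1 and 712032 in replicate 2. A count of 0 allows up to 3 reads, which is 7.55 CPM in replicate 1 and 4.21 in replicate 2. Shares of reads in 1 library carry 95% Wilson intervals, and values over both libraries are given as mean and standard deviation (SD, n = 2).

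The following choices were made before the data were examined. Genes with at least 10 reads summed over both libraries were compared by a two-sided exact binomial test of the gene's reads against the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05; log2 ratios had 0.5 added to each count. Correlations of log2 levels had 1 CPM added. The biological coefficient of variation was the square root of the common dispersion of edgeR with TMM scaling, with an interval from 100 bootstrap draws of genes. Transcript classes were compared by a two-sided Fisher's exact test over reads. Spliced models outside the annotation were matched between libraries by chromosome, strand and full intron chain. Use of annotated transcripts was compared by a two-sided Fisher's exact test of the gene's most read annotated transcript against its others, in genes with at least 20 annotated-transcript reads in each library. Genes with a second annotated transcript holding at least 20% in each library were counted apart. Replicate 2 was also thinned to the total of replicate 1 in 20 draws.

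The 20 gene lists were steroidogenesis, zona glomerulosa, zona fasciculata, X-zone, cholesterol synthesis, chromaffin cells, capsule and stroma, endothelium, macrophages, Schwann cells, red blood cells, adipocytes, kidney, liver, immediate early genes, heat shock, proliferation, glucocorticoid response, mitochondrially encoded genes and the circadian clock. Of their genes, Cyp11b2, Cyp11b1, Mc2r, Mrap and Per1 can count toward more than 1 list. For each list with at least 3 tested genes, the median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is not a test of conditions. Lists outside the 2.5th to 97.5th percentile are named. A further list of 29 liver genes was written after the first comparison and before its own values were seen.

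Genes were named by rule. The rule takes the 20 with the highest mean level and the members of the lists. Between the libraries it takes the 12 largest log2 ratios in each direction among genes past the threshold with at least 30 reads. It takes the 10 highest genes with a second annotated transcript in use, among all genes and among list genes, and up to 10 with the largest difference in transcript use past the threshold. Of spliced models outside the annotation it takes the 10 with the highest smaller count and those of steroidogenesis and chromaffin genes with at least 5 reads in each library, and of spliced antisense or intergenic loci the 5 highest. A gene outside the rule is said to be so where it appears.

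The tests were checked on simulated data built from the real totals and levels. Of 100 genes changed 2-fold, 61% were recovered, and of 100 changed 4-fold, 99% were. Of 9016 unchanged genes 8 passed, and 0 passed when no gene was changed. Of 20 unchanged lists 0 fell outside the central range, and 20 of 20 lists lowered 1.4-fold fell below it. Of 100 transcripts shifted by 30 points 56% were recovered, and of 1766 unshifted genes 1 passed. These rates for genes, lists and transcripts describe the simulated items only. Those simulations were not shown to hold a spread between animals, whereas the real libraries had a biological coefficient of variation of 14.1%. The rates are thus not error rates or power for the real tests, which include genes with few reads and lists of few genes. Simulated coefficients of variation of 0, 20 and 40% were recovered as 0.018, 20.0 and 39.6%.

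Alternatives tried were other read minimums, pseudocounts and scalings (TMM, DESeq2 size factors, a total without the 20 highest genes), annotated transcripts alone, models with 1 exon or under 2 reads left out, thinning, other classes and thresholds, and each library alone. Random lists matched also on transcript length, and the comparison of genes without 1-exon models, were added after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.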

Results

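Long-read RNA sequencing was used to catalogue the transcripts of the adrenal gland of female B6CASTF1/J mice at 25 days. Replicate 1 held 426150 reads and replicate 2 held 770041 reads, a depth ratio of 1.81. Added control RNAs took 2.08% of the reads of replicate 1 (2.04 to 2.13) and 1.88% of those of replicate 2 (1.85 to 1.91), 1.98% ± 0.15 (SD, n = 2). Annotated mouse genes held 95.2% and 94.2% of the mouse reads. The labels call the libraries biological replicates. The Wilson and counting intervals, limits and p-values below cover counting error only, because they hold no term for the spread between animals. Reads counted without molecular identifiers are not independent molecules, so these intervals can be too narrow even for counting error. A test between 2 libraries compares those libraries, not conditions.

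The most read genes of the gland were those of steroid hormone synthesis. Cyp11a1, the cholesterol side-chain cleavage enzyme that begins the pathway, was the highest gene at 26091 ± 2754 CPM (SD, n = 2), where CPM is the gene's reads scaled by the library's reads on annotated genes. Cyp21a1, the steroid 21-hydroxylase, followed at 16922 ± 153, and Star, which carries cholesterol into mitochondria, at 10250.3 ± 1926. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, stood at 9875 ± 712, and Cyp11b1, the 11-beta-hydroxylase that completes corticosterone synthesis, at 6983 ± 909.9. The list of 15 steroidogenesis genes took 8.22% of the reads on annotated genes in replicate 1 (8.14 to 8.31) and 7.38% in replicate 2 (7.32 to 7.44), a mean of 7.80% ± 0.60. With annotated transcripts alone the mean share was 5.86%. The top rank of Cyp11a1 holds with all models counted. Of annotated transcripts alone, Cyp21a1 had more reads in each library (5539 and 9558) than Cyp11a1 (4490 and 7175).

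In mm10 coordinates, Cyp11a1 (ENSMUSG00000032323.13) lies on chromosome 9 from 58006411 to 58027023 and Cyp21a1 (ENSMUSG00000024365.9) on chromosome 17 from 34801348 to 34804561. Star (ENSMUSG00000031574.8) lies on chromosome 8 from 25806555 to 25815982, Hsd3b1 (ENSMUSG00000027871.16) on chromosome 3 from 98852194 to 98859794, and Cyp11b1 (ENSMUSG00000075604.5) on chromosome 15 from 74834125 to 74841643. Highest of the other steroidogenesis genes was Scarb1, the lipoprotein receptor for cholesterol uptake, at 2591 ± 413 CPM. Fdx1 (1525 ± 244) and Nr5a1 (823 ± 65.0), the transcription factor SF-1, lay below it. The lowest by mean level were the corticotropin receptor Mc2r with 29 and 60 reads and Nr0b1 with 22 and 72. Cyp17a1, the 17-alpha-hydroxylase, had 3 reads in replicate 1 and 0 in replicate 2, which allows up to 4.21 CPM there. Reads of Cyp21a1 are hard to separate from those of its near-identical pseudogene Cyp21a2-ps, a gene outside the naming rule, which had 91 and 282 reads.

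Among the 20 most read genes were also markers of cell populations of the gland. Akr1c18, a 20-alpha-hydroxysteroid dehydrogenase of the X-zone, the transient inner cortex of young mice, stood at 7394 ± 238 CPM. Chga and Chgb, the chromogranins of the catecholamine granules of medullary chromaffin cells, stood at 5080 ± 362 and 3638 ± 647. Kcnk3, a potassium channel on the zona glomerulosa list, stood at 3782 ± 107. Counts of gland tissue cannot show in which zone it was read. The others were Adh1, Abcb1b, Fads2, Cebpb, Ubb, Sparc, Akr1cl, Fth1, Aldoa, Ctsb and Acly, between 5534 (Adh1, an alcohol dehydrogenase) and 2618 (Acly, ATP citrate lyase). Cyp11a1 alone held 2.80% and 2.41% of the reads, the 10 highest genes 9.96% and 9.19%, the 20 highest 13.0% and 12.4%, and the 100 highest 24.7% and 23.5%.

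**Figure D1:**
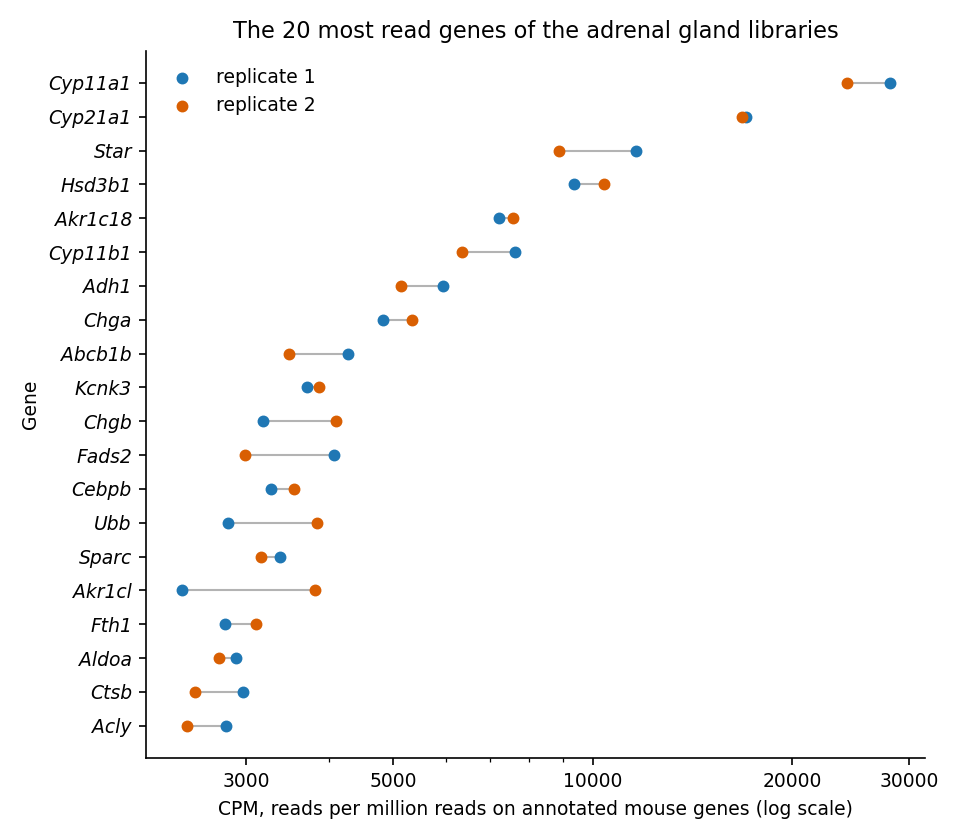
Level of the 20 genes with the highest mean, in CPM (reads scaled by the library's reads on annotated mouse genes) on a log axis, with 1 point per library and a line joining both. With all models counted, Cyp11a1 lies at 28038 in replicate 1 and 24144 in replicate 2, above the other 19 genes.

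Cortical zones and the medulla were all represented. The chromaffin list took 1.34% of reads in replicate 1 (1.30 to 1.38) and 1.48% in replicate 2 (1.45 to 1.505), with reads for 24 of 25 genes. Th, which makes the precursor of all catecholamines, had 2120 and 1694 CPM, and Pnmt, which turns noradrenaline into adrenaline, had 509 and 579. The zona fasciculata list took 1.47% and 1.15%, the X-zone list 0.829% and 0.868%, and the zona glomerulosa list 0.440% and 0.477%. Kcnk3 alone gave 1472 of the 1746 and 2747 of the 3396 reads of the zona glomerulosa list. The share of that list thus rests mostly on Kcnk3. Cyp11b2, the aldosterone synthase of the zona glomerulosa, had 65 and 218 reads, which is 164 and 306 CPM. The cholesterol synthesis list took 0.765% and 0.559%.

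Other cell types held smaller shares. Haemoglobin and other red blood cell genes took 0.308% and 0.368%, led by Hba-a1 with 622 and 1357 reads, whose reads are hard to separate from those of its near-copy Hba-a2. The adipocyte list took 0.240% and 0.198%, led by Cidea, a lipid droplet protein of brown fat, with 213 and 330 reads. Endothelial genes took 0.0713% and 0.0765%, macrophage genes 0.0254% and 0.0368%, capsule and stroma genes 0.0242% and 0.0312%, and Schwann cell genes 0.00176% and 0.00295%. The glucocorticoid response list took 0.0672% and 0.0661%, the immediate early list 0.0707% and 0.0608%, the heat shock list 0.624% and 0.439%, the circadian clock list 0.0760% and 0.109%, and the proliferation list 0.0121% and 0.0090%. Mitochondrially encoded genes took 0.109% and 0.103%. None of the 9 kidney genes, such as Umod and Kap, had a read in either library, which allows up to 7.55 and 4.21 CPM. The liver list took 0.0244% in replicate 1 (0.0200 to 0.0298) and 0.00014% in replicate 2 (2.5e-05 to 0.00080).

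Most annotated genes with reads were read in both libraries. Replicate 1 had reads on 13650 annotated genes and replicate 2 on 15328, and 12578 genes, 11419 of them protein-coding, were read in both. A further 3822 genes were read in 1 library only, 2418 of them with 1 read and 27 with at least 10. Replicate 2 thinned to the total of replicate 1 gave 13920 ± 33.7 genes (SD over 20 draws). With at least 5 reads required in each library, 8110 genes were read in both.

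The libraries were close but not identical in which genes they read most. The levels of 9271 genes with at least 10 reads correlated with Pearson's r of 0.916 and Spearman's rho of 0.914, across genes, which are not independent replicates. The biological coefficient of variation estimated by edgeR was 14.1% (13.3 to 15.02, bootstrap over genes). At the threshold, 199 genes differed, 2.15% of those tested, of which 125 were higher in replicate 1 and 74 higher in replicate 2. Without adjustment 1070 genes had a p under 0.05, and 72 of the 199 differed at least 2-fold. With TMM or DESeq2 scaling, which moved all log2 ratios by -0.05, 203 genes differed, 148 and 55 in those directions, and 180 of them were among the 199.

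**Figure D2:**
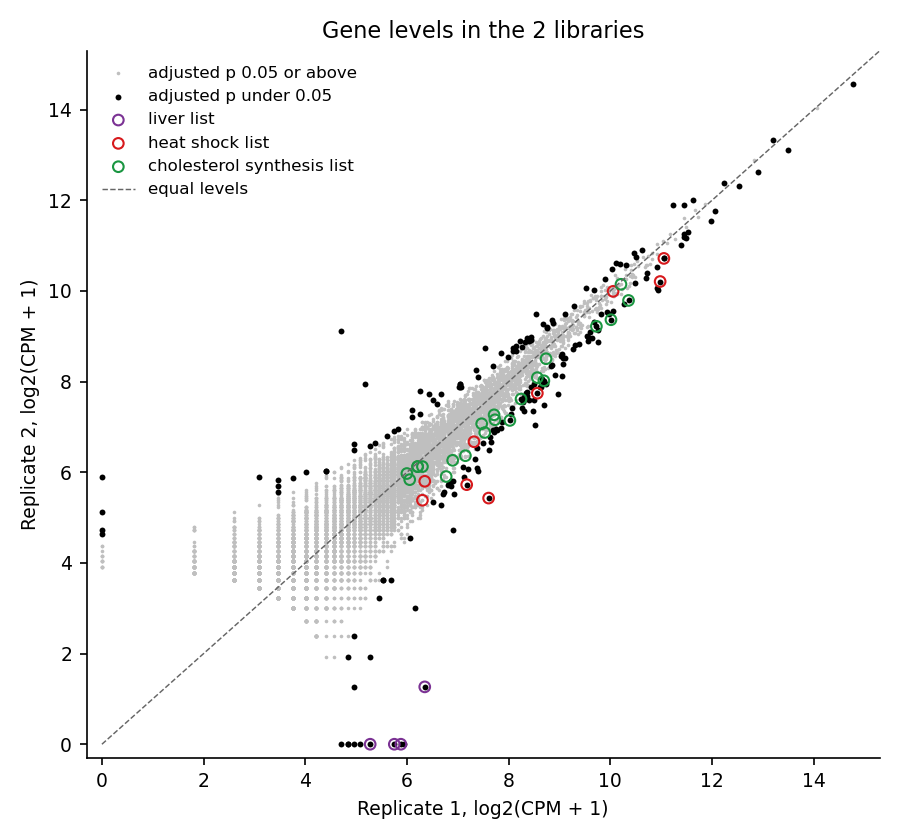
Level of each of 9271 genes in replicate 1 against replicate 2, as log2 of CPM plus 1, with genes at an adjusted p under 0.05 in black and the members of 3 lists ringed. The 4 tested liver genes lie at or near 0 in replicate 2, and all 21 cholesterol synthesis genes lie below the line of equal levels.

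Genes of cholesterol synthesis and of the heat shock response were higher in replicate 1 as groups. All 21 tested cholesterol synthesis genes had lower levels in replicate 2, with a median log2 ratio of replicate 2 over replicate 1 of -0.51, or 1.42-fold, a percentile of 0 among the random lists. Of these genes 6 passed the exact test over all genes and 11 when adjusted over the list alone. Dhcr7, which makes cholesterol in the last step of one branch, was 1.48-fold higher in replicate 1 (adjusted p = 2.0e-08 by the exact binomial test), Hmgcs1, which makes HMG-CoA, 1.57-fold (2.0e-08), and Idi1 1.85-fold. All 9 heat shock genes were lower in replicate 2, with a median log2 ratio of -0.77, or 1.71-fold, at percentile 0, and 5 passed over all genes and 7 when adjusted over the list alone.

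The largest ratio among heat shock genes was that of Hsph1, a chaperone of the HSP110 family, with 77 and 30 reads and 4.56-fold (adjusted p = 2.7e-11 by the exact binomial test). The inducible chaperone Hspa1b was 2.75-fold higher in replicate 1, though its reads are hard to separate from those of its near-copy Hspa1a. Hspa8, the constitutive HSC70, was 1.71-fold higher and Hsp90aa1 1.77-fold higher. Hspe1, the mitochondrial co-chaperonin, had 1063 and 1017 CPM and did not pass.

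Steroidogenesis genes were higher in replicate 1 by a smaller ratio. Their median log2 ratio was -0.22, or 1.16-fold, at percentile 0.315, with 6 genes higher in replicate 1 and 2 higher in replicate 2 over all genes, and 7 and 3 when adjusted over the list alone. Star was 1.31-fold higher in replicate 1 (adjusted p = 5.4e-39 by the exact binomial test), Mrap, the corticotropin receptor's accessory protein, 1.60-fold, Cyp11b1 1.20-fold and Cyp11a1 1.16-fold. Cyp11b2 was 1.86-fold and Hsd3b1 1.11-fold higher in replicate 2. With random lists matched also on transcript length, the percentile of this list was 2.98, inside the central 95%. Shorter genes were relatively higher in replicate 2: the median log2 ratio was 0.14 in the lowest quartile of genes by transcript length and -0.07 in the highest.

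The zona fasciculata list was also higher in replicate 1, with a median log2 ratio of -0.29 at percentile 2.27. Of its 5 tested genes 4 passed, over all genes and when adjusted over the list alone. Cyp11b1 and Mrap, which passed, and Mc2r, which did not, are also on the steroidogenesis list, so these lists are not separate results. Akr1b7, an aldose reductase-like enzyme of fasciculata cells, was 1.81-fold higher (adjusted p = 1.2e-27 by the exact binomial test) and Abcb1b, a drug efflux transporter, 1.23-fold. The zona glomerulosa list had a median of 0.33 at percentile 96.9, where Cyp11b2 passed over all genes and 2 genes when adjusted over the list alone. The X-zone list had a median of 0.08 at percentile 62.3 and 0 genes past the threshold.

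Chromaffin genes had a median log2 ratio of 0.22 at percentile 96.1. Chgb was 1.29-fold and Chga 1.11-fold higher in replicate 2, and Th 1.25-fold higher in replicate 1. With TMM scaling Chga no longer passed (adjusted p = 0.23 by the exact binomial test). The same numbers of genes, 2 and 1, passed when adjusted over the list alone. The adipocyte list had a median of -0.25 at percentile 2.25. Ucp1, the uncoupling protein of brown fat, was 1.88-fold higher in replicate 1 (adjusted p = 7.4e-08 by the exact binomial test), and adjusted over the list alone 3 genes were higher in replicate 1 and 1 in replicate 2. The macrophage list had a median of 0.65 at percentile 99.5, and 0 of its 9 tested genes passed either way. H2-Ab1, a class II antigen presentation gene, had 4 and 26 reads.

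Liver genes stood apart between the libraries. Alb, serum albumin, had 32 reads in replicate 1 and 1 in replicate 2, a log2 ratio of -5.28 with a counting interval of -11.19 to -3.26 (adjusted p = 6.3e-11 by the exact binomial test). The apolipoprotein genes Apoa1 (23 and 0 reads) and Apoa2 (21 and 0) were at least 13.7-fold and at least 12.5-fold higher in replicate 1, and Ttr, transthyretin, with 15 and 0 reads, at least 8.96-fold, each against the limit of 3 reads in that library. All 4 tested liver genes passed, over all genes and adjusted over the list alone. The list's median was at percentile 0, and with genes at 0 reads placed at their limit the median log2 ratio was -3.72.

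The remaining lists lay inside the central 95%. Red blood cell genes had a median log2 ratio of 0.22 at percentile 91.1, with Hba-a1 1.22-fold and Hbb-bs 1.26-fold higher in replicate 2, and these 2 genes also passed when adjusted over the list alone. With TMM scaling Hbb-bs no longer passed (adjusted p = 0.077 by the exact binomial test). The circadian clock list had a median of -0.12 at percentile 20.0 and a higher share of reads in replicate 2, because Dbp, a clock-controlled transcription factor, held 148 and 510 of its reads. Dbp was 1.92-fold higher in replicate 2 (adjusted p = 9.0e-11 by the exact binomial test) and was the one gene of its list past the threshold, over all genes and adjusted over the list alone. The immediate early list (median -0.25, percentile 6.88), the proliferation list (-0.15, 34.0), the glucocorticoid response list (-0.11, 20.5), mitochondrially encoded genes (0.02, 48.9), the endothelial list (0.08, 62.2) and the capsule and stroma list (0.15, 69.3) had 0 genes past the threshold, over all genes and adjusted over the list alone. The Schwann cell list had 1 tested gene and the kidney list 0, so neither was placed. In all, 7 of 18 lists lay outside the central 95%, where 0.9 would by chance if genes were independent, which was not tested. Some of these lists share genes.

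**Figure D3:**
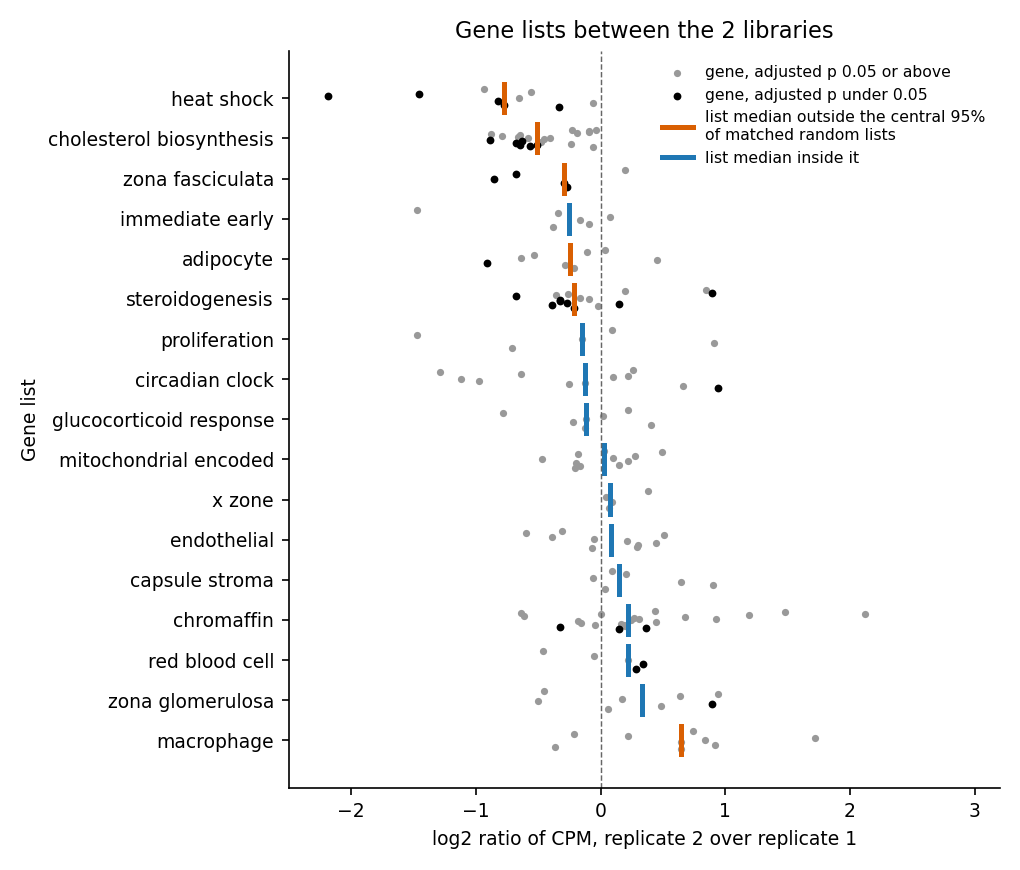
Log2 ratio of CPM, replicate 2 over replicate 1, for the tested genes of 17 lists, with 1 point per gene, black at an adjusted p under 0.05, and a bar at each list's median. The liver list is left off because 3 of its genes had 0 reads in replicate 2; the heat shock and cholesterol synthesis medians lie at -0.77 and -0.51.

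Among the 12 named genes with the largest ratios toward replicate 1 was Srxn1, which repairs oxidised peroxiredoxins (ENSMUSG00000032802.8, chromosome 2 from 152105516 to 152111376), with 145 and 93 reads, 2.79-fold (adjusted p = 3.7e-12 by the exact binomial test). Pdk4, a kinase that restrains glucose oxidation, was 2.46-fold higher, Pim1, a serine/threonine kinase, 2.60-fold, and Rbp4, the retinol carrier, 2.64-fold. Ptp4a1, a phosphatase whose name is shared by another gene identifier, was 2.38-fold higher, Sf1, a splicing factor, 2.68-fold, and Fam129a 2.88-fold. Alb, Hsph1 and Hspa1b, given above, also belong to this set of 12. The last members were Gm7247 (28 and 5 reads) and Aldh18a1 (47 and 18 reads), which rested on 1-exon models for 100% and 60% of their reads. Without 1-exon models the log2 ratio of Aldh18a1, which makes a proline precursor, was 0.04 in place of -2.20, and with annotated transcripts alone it was 0.30.

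Toward replicate 2 the 2 largest ratios belonged to genes whose reads all came from 1-exon models. Gm14303, a processed pseudogene of 1 exon (ENSMUSG00000081344.5, chromosome 2 from 172509521 to 172509691), had 10 and 397 reads, 21.1-fold (adjusted p = 5.1e-58 by the exact binomial test). Gm20659, an antisense gene (ENSMUSG00000093467.1, chromosome 11 from 101971143 to 101971859), had 0 and 42 reads, at least 7.81-fold against the limit of 3 reads. The antisense gene Tbx3os1 had 14 and 174 reads and Mir1906-1, within the Meg3 region, had 4 and 40, and 94.7% and 100% of these reads came from 1-exon models. Mmp14, a membrane-bound matrix metalloproteinase, had 3 and 42 reads, a log2 ratio of 2.76 with a counting interval of 1.32 to 5.30. Apool, Usf1, Cyba, Aaed1, Unc119, Sdhaf1 and Fbxo25 were between 4.52-fold and 3.05-fold higher. Replicate 1 held 12 reads or fewer of each of these 7 genes. Of the 24 genes named by the rule, 14 stayed past the threshold in every setting that gave a value. Aldh18a1, Fam129a, Rbp4, Tbx3os1, Apool, Usf1, Cyba, Aaed1, Sdhaf1 and Fbxo25 did not in at least 1. Among the 14, Gm7247 and Gm20659 gave no value with annotated transcripts alone or without 1-exon models. Gm14303, Mir1906-1 and Hspa1b gave none without 1-exon models, so these settings could not test them.

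With all models counted, the share of each transcript class differed by less than 1 point between the libraries. Annotated transcripts held 73.4% of mouse reads in replicate 1 (73.2 to 73.5) and 72.6% in replicate 2 (72.5 to 72.7), and incomplete splice matches 8.69% and 8.78%. Unannotated combinations of annotated splice sites held 4.42% and 4.37%, models with an unannotated site 3.24% and 3.18%, and genomic models 5.61% and 5.57%. Antisense models held 3.82% (3.76 to 3.88) and 4.73% (4.68 to 4.78), a difference of 0.911 points (adjusted p = 8.5e-119 by Fisher's exact test), and intergenic models 0.858% and 0.800% (adjusted p = 0.0022 by Fisher's exact test). Annotated transcripts differed by -0.793 points (adjusted p = 7.3e-20 by Fisher's exact test), and the other 4 classes did not pass. With 1-exon models left out, the differences of the annotated and intergenic classes no longer passed, that of incomplete matches did, and that of the antisense class was 0.0463 points. With models under 2 reads left out all 7 classes passed. Differences were then -2.04 points for annotated transcripts, 1.08 for antisense models and 0.460 for incomplete matches. The combination, unannotated-site and genomic classes turned toward replicate 2. In every class the shallower replicate 1 had the larger share of models with 1 read, such as 73.2% against 66.0% of antisense models. This minimum thus took out a larger share of its models, and depth was not separated from these differences.

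Single genes shaped some of these classes. Of the Cyp11a1 reads, 52.2% in replicate 1 and 52.3% in replicate 2 belonged to 1 genomic model of 1 exon at the end of the gene, from 58023966 to 58027023 in replicate 1, and this model alone held 24.9% and 21.4% of all genomic reads. Of the Hsd3b1 reads, 79.4% (78.1 to 80.7) and 78.0% (77.1 to 78.9) belonged to a model of 4 exons that matched the end of an annotated chain and began at 98858341 on the minus strand, whereas annotated Hsd3b1 transcripts held 1.34% and 0.758%. For comparison, annotated transcripts held 81.9% and 79.8% of the Cyp21a1 reads and 87.3% and 87.3% of the Cyp11b1 reads.

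**Figure D4:**
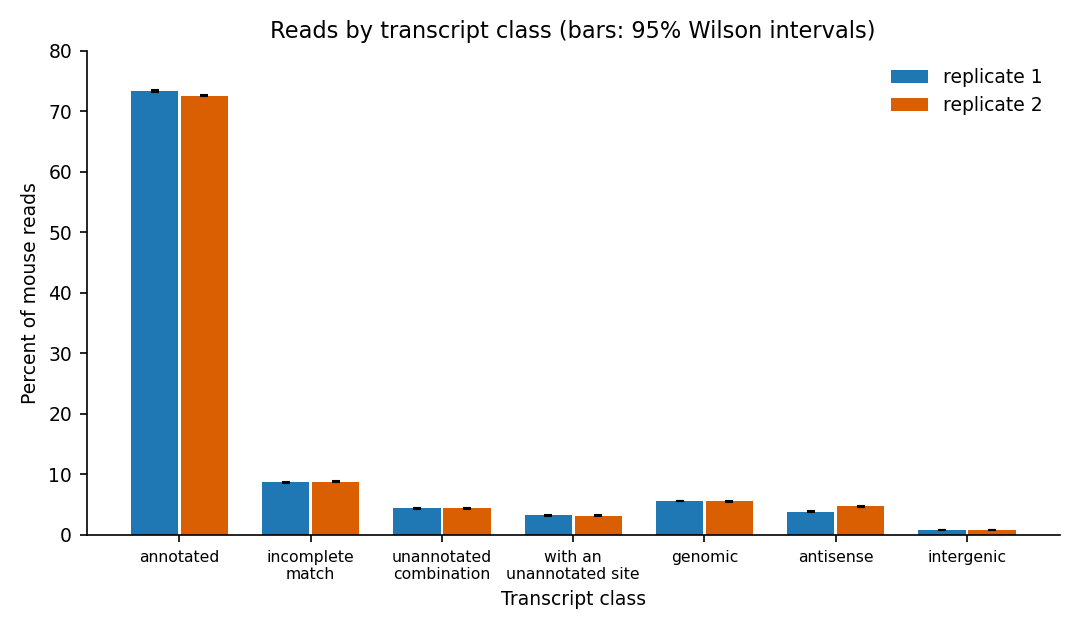
Share of mouse reads by transcript class in percent, with 1 bar per library and 95% Wilson intervals. Annotated transcripts hold 73.4% and 72.6%, and antisense models 3.82% and 4.73%.

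Spliced transcripts outside the annotation were numerous, and the share of the gene's reads held by the best supported ones varied by gene. Of 19492 such intron chains in replicate 1 and 30813 in replicate 2, 5933 were found in both. With at least 2 reads in each library 1968 were found in both, and with at least 5 reads 564. A chain of the combination class read once in replicate 1 was found in replicate 2 in 25.8% of cases (24.8 to 26.8), one read 6 to 10 times in 93.5% (89.6 to 96.0) and one read 11 times or more in 87.4% (80.8 to 92.0). For chains with an unannotated site these shares were 13.6%, 76.7% and 90.6%. Of such chains found in both libraries, 36.5% had that site within 10 bases of an annotated one. Among those found in 1 library only, the shares were 37.5% in replicate 1 and 35.0% in replicate 2. Being found in both thus did not go with fewer sites close to annotated ones.

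The highest was a 5-exon chain of Oaz1, the antizyme that limits polyamines, with 723 and 1413 reads, 94.4% and 93.9% of the gene (chromosome 10 from 80826656 to 80829290). It differed from the closest annotated transcript, Oaz1-201, by a gap of 4 bases that the annotation holds as an intron and the reads did not. The chain of its paralog Oaz2, with 84 and 155 reads, lacked the same kind of 4-base gap. Antizyme genes are known for a programmed shift of reading frame. The chain of Phb2, a mitochondrial prohibitin, with 121 and 209 reads, skipped an annotated exon of 6 bases. Mrpl33, a mitochondrial ribosomal protein gene, had a 3-exon chain with 126 and 301 reads and an unannotated splice site. Mpc1, of the mitochondrial pyruvate carrier, had a 4-exon chain with 96 and 171 reads that joined annotated sites over an intron outside the annotation. The remaining chains of the 10 belonged to Cdkn1c, Cyb561, Ctbp1, Idh3g and Cct6a, with 117, 95, 86, 80 and 76 reads in replicate 1. The chain of Cdkn1c, an inhibitor of the cell cycle, held 19.7% and 24.6% of its gene.

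Among genes of steroidogenesis, 175 such chains were found in both libraries, 42 with at least 5 reads in each, and they held 3.40% and 3.45% of the list's reads over 13 genes. Chromaffin genes had 45 such chains, 14 with at least 5 reads in each, holding 6.04% and 5.39% over 9 genes. Cyb561, the cytochrome that supplies electrons inside chromaffin granules, had the highest, a 6-exon chain with 95 and 188 reads, 55.6% and 54.7% of the gene (chromosome 11 from 105933702 to 105940164). In Cyp11a1 the highest chain had 65 and 110 reads, 0.584% and 0.640% of the gene. In Nr5a1 the highest had 24 and 10 reads, 6.96% and 1.81%.

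Spliced antisense and intergenic loci were rarer. Of 518 and 974 such chains 105 were found in both, 72 antisense and 33 intergenic. The highest was a 3-exon chain antisense to Mc2r, with 46 and 90 reads on the plus strand of chromosome 18 from 68406907 to 68429320, compared with 29 and 60 reads of Mc2r itself. Its ends equal those of Mc2r, so that its strand is uncertain. The next were antisense to Mbnl1 (23 and 28 reads), Crebbp (12 and 31) and Nr2f2 (11 and 18), and 1 intergenic chain on chromosome 10 (12 and 18) lay 87665 bases from Gm36719.

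Few genes used annotated transcripts differently in the libraries. Of 1866 tested genes 3 differed, and 61 had an unadjusted p under 0.05. Rsrp1, an arginine and serine-rich protein gene (ENSMUSG00000037266.18, chromosome 4), had 62.8% of its annotated-transcript reads in replicate 1 (57.9 to 67.4) and 85.9% in replicate 2 (83.1 to 88.3) on Rsrp1-204, a transcript with a retained intron (adjusted p = 2.1e-14 by Fisher's exact test). Cox4i1, a subunit of cytochrome c oxidase, had 46.1% and 57.0% on the coding transcript Cox4i1-201 against the retained-intron transcript Cox4i1-204 (adjusted p = 0.00039 by Fisher's exact test). Atp5d, a subunit of ATP synthase, had 87.1% and 97.7% on Atp5d-201 (adjusted p = 0.00044 by Fisher's exact test). The median absolute difference over all tested genes was 2.52 points. With incomplete splice matches added 31 genes differed.

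A second annotated transcript was in regular use in 317 of 3057 genes with enough reads, or 10.4%. Scg2, a granin of chromaffin cells, was split between Scg2-202, with 54.3% and 51.7%, and Scg2-201. Fdps, of cholesterol synthesis, had 71.7% and 71.6% on Fdps-201. Gnas, the stimulatory G protein through which corticotropin acts, had 55.5% and 59.4% on Gnas-208, and Pkm, pyruvate kinase, had 79.1% and 79.5% on Pkm-201. Acly, Map1lc3a, Ddx5, Fkbp8, Cox4i1 and Hsd3b1 complete the 10 highest, and Hsd3b1 rests on 50 and 56 annotated-transcript reads. Among list genes Hmgcs1, with 59.9% and 64.3% on Hmgcs1-201, Pik3c2g, Cfd, Cidec, Plin1, Egfl7 and Sgk1 also met the rule. The count rests on both libraries having to pass: replicate 2 alone gave 631 genes and replicate 1 alone 390.

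**Figure D5:**
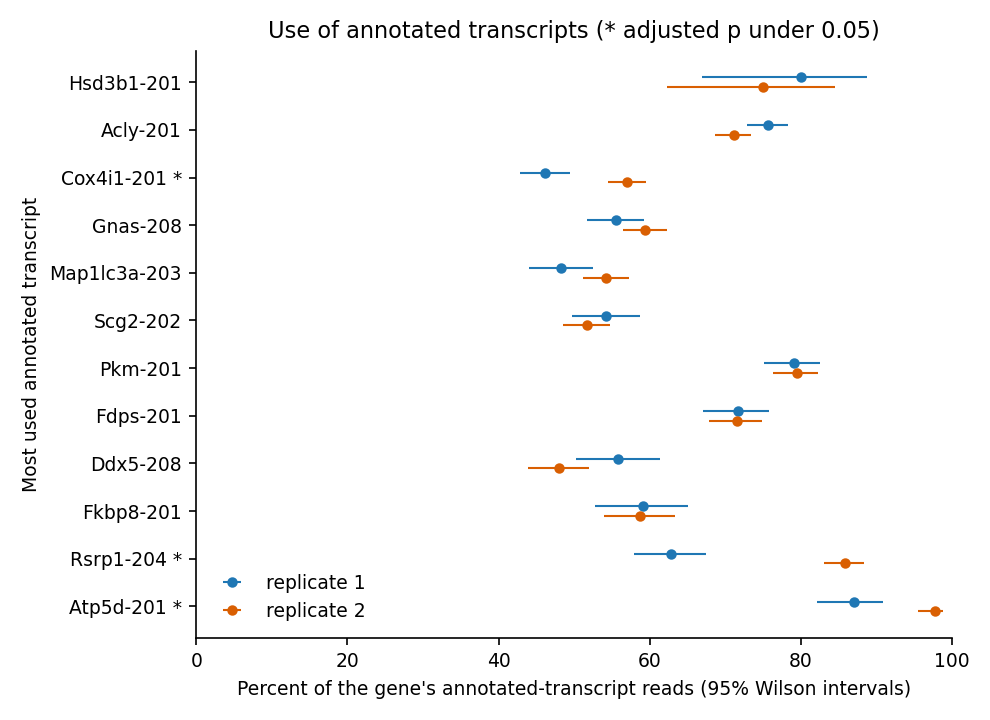
Share of each gene's annotated-transcript reads held by its most used annotated transcript, in percent, per library with 95% Wilson intervals, for the 10 highest genes with a second transcript in use and for 2 further genes that differed. Rsrp1-204 lies at 62.8% and 85.9%, Atp5d-201 at 87.1% and 97.7%, and Pkm-201 at 79.1% and 79.5%.

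The added control RNAs, which were the same mix in both libraries, did not differ at the threshold. Of 28 control species with at least 10 reads 0 passed the exact binomial test, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.097. Their log2 values correlated with Pearson's r of 0.981 across species.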

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

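The checks of scaling and the tests of fat tissue and of the strand error rate were chosen after the results were seen. No biological explanation was tested, because the design has 1 group.

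Reads appeared in records that the comparisons between the libraries did not use, above the 3 reads that a count of 0 allows. On chromosome Y, outside annotated genes, the female-labelled libraries held 60 reads in replicate 1 and 82 in replicate 2, of which 46 and 53 lay at 1 locus from 43918755 to 43923547. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 reads in both. On the antisense strand of the added control RNAs lay 59 reads in replicate 1 and 128 in replicate 2.

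Antisense models held 3.82% and 4.73% of mouse reads. The control RNAs, which have no natural antisense partner, gave 0.665% (0.516 to 0.856) and 0.886% (0.746 to 1.05), so strand errors at that rate could account for only part of the 3.82% and the 4.73%. A constant share of each gene's own reads on the wrong strand was also argued against: per own read, genes between the 40th and 60th percentile of reads had 9.51 times (replicate 1) and 9.53 times (replicate 2) as many antisense reads as the most read decile. What stays open is a mixture of transcribed antisense RNA, with or without internal priming on that RNA, and strand errors that differ by gene. Of the antisense reads, 96.8% and 96.6% came from 1-exon models.

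Liver transcripts were read in replicate 1 and almost not in replicate 2. Scaling shifts all genes alike, so it cannot set a list apart from random lists matched on expression. The percentile of 0 of the 4 tested liver genes was the result itself, not a separate test of scaling. With TMM scaling all 4 still passed, Alb with a log2 ratio of -5.33. Liver RNA in the replicate 1 library is a candidate source that these counts leave open: the 29 further liver genes had 3.37 times the CPM in replicate 1 (counting interval 2.63 to 4.34), between the bounds of 5 and 2 set beforehand. All 24 genes of that list that were read had reads in replicate 1 and 5 had reads in replicate 2, where Apoc4 and Cyp2e1 held 60 and 31 of the 100 reads, beside 45 and 18 in replicate 1. The most abundant of the others in replicate 1 were Serpina3k (24 reads), Ahsg (12) and Serpina1c (11), each with 0 in replicate 2.

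All 21 tested cholesterol synthesis genes were higher in replicate 1. Scaling shifts all genes alike, so it cannot set a list apart from random lists matched on expression. The percentile of 0 there was the result itself, not a separate test of scaling. Transcript length as the whole cause was argued against by a percentile of 0 among random lists matched on expression and length. More fat tissue in replicate 1 could not be told apart: the adipocyte list had a median log2 ratio of -0.25, and its bootstrap interval over 8 genes, -0.64 to 0.04, holds the cholesterol median of -0.51. A difference between the animals stays open and untested.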

How the results depend on the processing

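Random lists matched also on transcript length, and the comparison of genes without 1-exon models, were chosen after the results were seen. Of 238 values under alternatives, 188 kept their direction and their side of the threshold or moved by less than the spread. Of the others, 40 moved, 4 came to pass, 3 no longer passed and 3 reversed. A share from 1 library alone always lies within the SD of both libraries, so those values counted among the 188 by construction. So did list percentiles under TMM and DESeq2 scaling, because a uniform scaling cannot change them. The count of genes differing stayed between 134.75 (replicate 2 thinned, mean of 20 draws) and 203 except for the 2-fold threshold, and 7 lists lay outside the central range under each of 4 alternatives, not always the same lists. Of 183 values of the 24 named genes, 157 kept direction and threshold, 24 no longer passed and 2 reversed. With at least 30 reads the liver and proliferation lists had too few genes to be placed. Of the models, 64.2% and 62.8% had 1 read. Unless said otherwise, the cause was not tested.

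With at least 5 reads in each library 8110 genes were read in both, by construction. Pearson's r was 0.893 with 0.1 and 0.947 with 10 CPM added, 0.897 without a filter and 0.943 from 100 reads, where the coefficient of variation was 13.3%. A 2-fold minimum left 72 genes, by construction. Aldh18a1 had a log2 ratio of 0.30 with annotated transcripts alone and 0.039 without 1-exon models, since its difference lay in a 1-exon model. With annotated transcripts alone, mean shares were 5.86% for steroidogenesis, 0.883% X-zone, 1.57% chromaffin, 0.0216% capsule and stroma, 0.427% red blood cells, 0.0800% immediate early, 0.0615% glucocorticoid response and 0.138% mitochondrially encoded. With lists matched on length, the steroidogenesis percentile was 2.98 and that of zona glomerulosa 98.8, and with at least 30 reads the latter was 98.1.

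Without 1-exon models, class shares were 81.9% annotated, 5.22% unannotated combination, 3.81% unannotated site, 0.140% genomic, 0.168% antisense and 0.0674% intergenic, by construction. Differences between the libraries were then -0.170 points for annotated, 0.169 for incomplete match, 0.0463 for antisense and -0.0016 for intergenic models. Without models under 2 reads, shares were 79.4% annotated, 7.11% incomplete match, 3.00% combination, 1.46% unannotated site, 5.20% genomic, 3.29% antisense and 0.574% intergenic. Differences were then -2.04 points for annotated transcripts, 0.460 for incomplete match and 0.188 for combination. They were 0.260 for unannotated site, 0.103 for genomic and 1.08 for antisense models. Unequal depth was not separated from these differences. The shared chains outside the annotation numbered 1968 from 2 reads, 564 from 5 reads, 3610 for combinations and 1862 for unannotated sites, by construction. Transcript use differed in 6 genes with chains outside the annotation added, in 31 with incomplete matches added, and in 1 at 20 points or more. Genes with a second transcript in use numbered 511 at 10%, 154 at 30%, 504 from 10 reads and 117 from 50 reads, and 390 to 631 in 1 library alone.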

Other observations

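The genes in this part, apart from Fads2, Acly and those of the adipocyte list, lie outside the naming rule and were chosen after their values were seen; no test of an explanation was made here. Those of fatty acid metabolism and the chaperones were picked because they passed the threshold, no list of their pathways was tested, and they say nothing of other members. Scd1, a stearoyl-CoA desaturase, had 355 and 162 CPM (log2 ratio -1.14, adjusted p = 1.1e-07 by the exact binomial test), and Scd2 had 393 and 236. Fads1 and Fads2, which desaturate polyunsaturated fatty acids, had log2 ratios of -0.68 and -0.44, and Elovl5, an elongase, had -0.55. Me1 and Acly, which supply NADPH and acetyl-CoA for fatty acid synthesis, had -0.39 and -0.20. Some of these genes are also typical of fat tissue. The adipocyte list had a median log2 ratio of -0.25, with a bootstrap interval over its genes of -0.64 to 0.04. Ucp1, which passed, was 1.88-fold higher in replicate 1. Adjusted over the list alone, Cidec and Plin1 also passed toward replicate 1, with log2 ratios of -0.64 and -0.53, and Cfd toward replicate 2, with 129 and 318 reads and a log2 ratio of 0.46.

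Among single chaperone genes outside the heat shock list that passed the threshold, Hsp90ab1 had a log2 ratio of -0.37, Hsp90b1 of the endoplasmic reticulum -0.59, the co-chaperone Stip1 -0.76 and Hspb8 -0.87. Cirbp, an RNA-binding protein induced by cold, was higher in replicate 2, with 30 and 157 reads and a log2 ratio of 1.53 (adjusted p = 7.0e-07 by the exact binomial test). Agtr1a, an angiotensin receptor, had 41 and 32 reads and a log2 ratio of -1.19.

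Xist, which is transcribed from the inactive X chromosome of females, had 10 reads in replicate 1 and 41 in replicate 2. Genes with the most antisense reads were Gm26917, with 758 and 1287 antisense reads against 81 and 92 of its own, and Actb, with 209 and 648 against 444 and 889.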
